A study of Homo sapiens with 12 samples.

How the data were processed

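CUT&RUN with an AHR antibody or IgG was done on primary human CD4+ memory T cells with a kit protocol, per the labels' protocols, and 12 libraries fall into 4 groups by guide and antibody, 3 each. Groups, replicate numbers and the dose and time came from the labels. Peak lists of the 6 AHR libraries and 1 region table with 4 columns were used, and files of the 6 IgG libraries were not analysed here.

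The submitters' processing notes name FastQC, Bowtie2, SAMtools, Picard, SEACR, bedtools, ChIPseeker, DiffBind, DESeq2 and HOMER and the builds GRCh38 and hg38, with no versions or order. Which of them made which file, the peak threshold, the use of IgG as a control in peak calling and the handling of duplicate or multiply mapped reads are not given in the sources used here. The deposited peak lists have the layout that SEACR writes, 1 list per library, and give for each peak the total and the maximum of a coverage signal. Per library, all of these deposited maximum signals were, within a small rounding error, whole multiples of 1 value. It is taken here as the value of 1 fragment and called the coverage step. What the authors divided the coverage by is not given in the sources used here. The deposited region table gives a normalized signal for 8828 analysed regions of 401 bp in replicates 1 and 2 of each guide, per the file headers. Its deposited values were whole multiples of 1 value per library for 100.0% of entries (tolerance 0.001 reads), so whole reads were recovered by division, and each library had been scaled to the same total over the table. Such scaling removes a difference in total between the guides and raises sites that did not change when many others fall.

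Chromosome Y and 50 kb on either side of XIST were left out throughout. Coordinates of BED files were turned to 1-based. Regions were assigned to the nearest of 19974 protein-coding genes of RefSeq (GRCh38.p14) within 50 kb by gene body, which gave 7962 regions a gene, and 715 regions overlapped more than 1 gene. The gene table used here has no strand, so the planned promoter class was replaced by regions within 1000 bp of either gene end (4472 regions). Assignment by distance does not show which gene a region regulates. Motif classes and GC content were not analysed here, since no genome sequence was used. Planned fits with a batch term or without replicate 3 have no counterpart in the table, which holds replicates 1 and 2 only, and the planned 3 against 3 comparison became 2 against 2.

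Differences between guides were fitted with limma 3.58.1 in R 4.3.3 on log2 of the deposited value plus a pseudocount of 1, with an intensity trend and no block, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes on this scale understate the change of weak regions. Gene lists, fixed before the data were examined along with the tests, alternatives and naming rule, were tested with camera at the preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 13 lists of at least 2 regions. They covered canonical AHR targets, the AP-1 family, T follicular helper and CXCL13, Th17 and Th22, Th1, Th2, regulatory T cell, type I interferon, T cell activation, tissue residency and migration, B cell, monocyte, natural killer and CD8, and housekeeping genes. Some genes are on more than 1 list. Peak numbers were compared by an exact two-sided permutation test, and peak sharing by bedtools 2.31.1 with at least 1 bp of overlap and 95% Wilson intervals. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9 did the rest.

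Regions were named by a rule. It takes the 10 lower regions with the smallest p in which every sgAHR library lay below every sgNT library, and the same for higher regions, with the 5 smallest p named where fewer than 5 pass. It adds, for 20 genes of interest, the region with the highest mean, and up to 3 members per list with the smallest p. NFE2L2 was named after its values were seen. Some regions that the rule takes are not reported here.

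Alternatives were edgeR 4.0.16 quasi-likelihood and DESeq2 1.42.0 on the recovered reads, other pseudocounts, a filter on low regions, median centring, quantile and TMM scaling, library weights, the replicate number as a block, each library left out in turn, an estimated correlation for the lists and fry, which tests whether the regions of a list move one way on balance and does not compare them with other regions, and other reaches of assignment. Scaling by the coverage step, TMM factors in edgeR, the size factors of DESeq2, the subset with peaks under both guides and common peak thresholds were chosen after seeing the data. The limma step was tested on simulated data for the sgAHR against sgNT comparison with 2 libraries each, 8828 regions and 200 of them changed. It recovered 0.00% of 2-fold, 6.90% of 4-fold, 27.3% of 8-fold and 35.7% of 16-fold losses, and 0.00%, 33.3%, 96.4% and 100.0% of gains of the same sizes, with 1 false call among 75. With no change simulated it made 0 calls, and camera gave an unadjusted p under 0.05 for 1.50% of random sets. The simulated regions were drawn independently, so this share does not cover lists whose regions move together. The estimated correlation was 0.254 in the list of canonical AHR targets. At this depth, 7 to 14 reads in the median region, and with 2 libraries per guide, most simulated losses were not recovered.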

Results

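The aryl hydrocarbon receptor (AHR) is a transcription factor that enters the nucleus and binds DNA when a ligand such as the dioxin TCDD occupies it. Its binding was mapped by CUT&RUN, in which an antibody tethers a nuclease to chromatin so that fragments near the bound protein are released and sequenced. The cells were primary human CD4+ memory T cells that had received a guide RNA against AHR (sgAHR) or a non-targeting guide (sgNT) by nucleofection and were then stimulated with CD3/CD28 beads and 3 nM TCDD for 72 hours. The labels list 12 libraries, 3 per guide with the AHR antibody and 3 per guide with control IgG. The 6 AHR libraries each have a peak list, and a region table holds normalized reads for replicates 1 and 2 of each guide. No IgG library was analysed here, so no background measured with IgG stands beside the values. The question set by the design was which AHR sites depend on AHR itself. The guide acts on the AHR gene, and binding of AHR to chromatin near its own gene does not report how much protein was left, so the data hold no direct check of the edit. The labels do not say that replicates came from separate donors or cultures. The p-values of the region fits and of the peak numbers therefore measure only the spread between these libraries, which may be technical. Fisher and shuffling p-values take regions as the units, and camera sets regions against other regions. None of them measures a spread between donors.

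Depth differed between the guides inside the analysed regions. Over 8828 regions of 401 bp, sgNT replicates 1 and 2 held 156878 and 164176 recovered reads, and sgAHR replicates 1 and 2 held 80075 and 116672. The mean was 160527 ± 5160 reads under sgNT and 98374 ± 25878 under sgAHR (SD, n = 2 each), a ratio of 1.63. Of these regions, 5252 had a peak in sgNT lists of replicates 1 and 2 only and 556 in sgAHR lists only. The choice of regions therefore enters this ratio. The median region held 14 reads in both sgNT libraries and 7 and 8 reads in the sgAHR libraries, and 21 and 25 regions against 143 and 140 regions held 0 reads. The value of 1 fragment in the coverage behind the peak lists was nearly the same in all 6 libraries, with the largest 1.16 times the smallest. The deposited values give every library the same total over the regions of the table, so a loss common to all sites is not visible in them.

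AHR peak lists were shorter in cells with the AHR guide. The sgNT lists held 6944, 5579 and 4121 peaks and the sgAHR lists held 2212, 2768 and 15, so that every sgAHR list was shorter than every sgNT list. The means were 5548 ± 1412 under sgNT and 1665 ± 1456 under sgAHR (SD, n = 3 each), a difference of -3883 peaks with an exact two-sided permutation p of 0.1, the smallest that 3 against 3 libraries can give. Replicate 3 of both guides carries another source label than replicates 1 and 2, and the sgAHR list was shorter within both sets, with 2212 and 2768 against 6944 and 5579 peaks in replicates 1 and 2 and 15 against 4121 in replicate 3. Without sgAHR replicate 3 the sgAHR mean was 2490 ± 393 (SD, n = 2) and the difference -3058, with an exact permutation p of 0.2, the smallest possible there.

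The signal of the weakest listed peak differed between the lists. The weakest peak of sgAHR replicate 3 had a total of 28699 fragment-bp, the coverage summed over its bases, against 3029 to 3981 in the other 5 lists. At a common threshold, set by the highest of the weakest peaks of the other 5 lists, 5973, 5579 and 2968 sgNT peaks stood against 1870 and 2740 sgAHR peaks (difference -2535, exact permutation p = 0.2). At the threshold of sgAHR replicate 3 the numbers were 79, 88 and 31 against 18, 75 and 15 (difference -30, exact permutation p = 0.2), so among the strongest sites the groups overlapped.

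**Figure D1:**
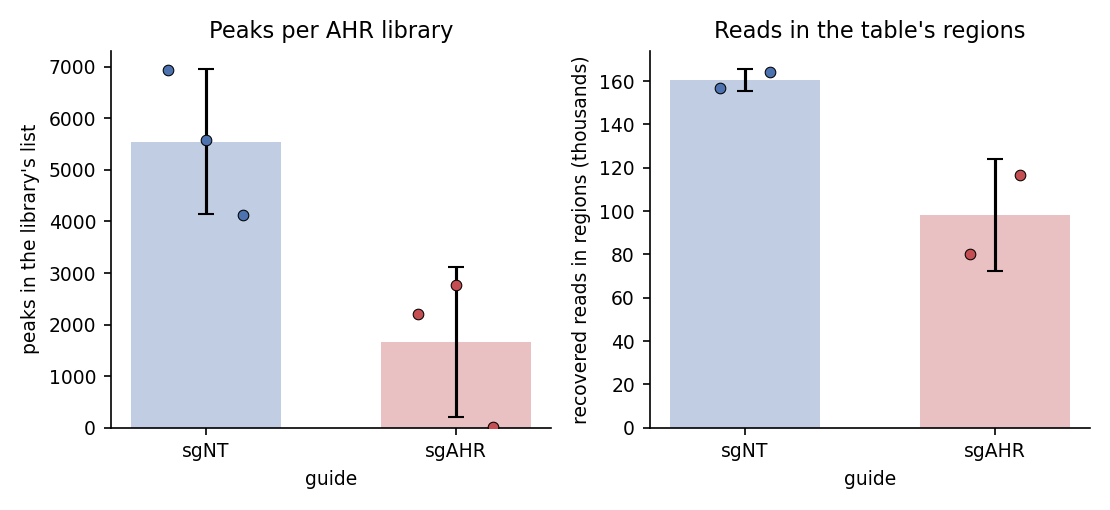
Left, number of peaks in each AHR library's list by guide; right, recovered reads (axis in units of 1000) in the regions of the table by guide. Points are libraries, bars means and error bars 1 SD (n = 3 per guide for peaks and n = 2 for reads). The 3 sgNT lists hold 4121 to 6944 peaks, above the 3 sgAHR lists with 15 to 2768.

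Most peaks that remained under the AHR guide were also sgNT peaks. Of the 2212 peaks of sgAHR replicate 1, 79.3% (95% Wilson interval 77.6% to 81.0%) overlapped a peak of sgNT replicate 1, whereas 25.3% (24.3% to 26.4%) of the peaks of sgNT replicate 1 overlapped a peak of sgAHR replicate 1. Between sgNT replicates 1 and 2 the shares were 60.2% and 74.3%, and 80.0% of sgNT replicate 3 peaks lay in sgNT replicate 1. The 6 lists merged into 9377 places, of which 4910 were found in at least 2 sgNT lists. Of these, 2436 (49.6%, 95% Wilson interval 48.2% to 51.0%) were in 0 sgAHR lists, 1269 in 1, 1193 in 2 and 12 in 3. Places in at least 2 sgAHR lists and in no sgNT list numbered 28, or 55 without sgNT replicate 1 and 107 without sgNT replicate 2. All 15 peaks of sgAHR replicate 3 overlapped a peak of sgNT replicate 3, so the 28 could come only from sgAHR replicates 1 and 2. The number without either of these was 0, as that overlap fixed in advance. The 28 and the 2436 therefore do not compare evenly. The share of sgNT places absent from all sgAHR lists reflects list length as well as signal, and all intervals cover counting error only.

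Among known AHR target genes, regions of CYP1A1, CYP1B1 and AHRR were lower in the sgAHR libraries. At CYP1A1, the dioxin-inducible xenobiotic monooxygenase, a region 613 bp outside the gene body (hg38 chromosome 15, 74726141 to 74726541) held 73 and 71 reads under sgNT and 13 and 9 under sgAHR. Its log2 difference in normalized reads was -1.93 ± 0.39 (SE, n = 2 per guide, limma adjusted p = 0.0131). Regions near its relative CYP1B1 fell by 1.98 (chromosome 2, 38076685 to 38077085, 534 bp outside the gene body, adjusted p = 0.0213) and fell by 1.82 (38096317 to 38096717, 20166 bp outside, adjusted p = 0.0379) on the log2 scale. A region inside AHRR, the gene of the AHR repressor, fell by 1.95 (chromosome 5, 399814 to 400214, adjusted p = 0.0263). A region inside BATF, an AP-1 family factor of T helper cells, held 29 and 14 reads against 1 and 1 and fell by 2.88 (chromosome 14, 75522332 to 75522732, adjusted p = 0.035). The BATF region with the highest mean, also inside the gene (75542931 to 75543331), had a log2 difference of -0.37 and did not pass (adjusted p = 0.768).

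The region with the smallest p lay 9392 bp outside LEKR1 (chromosome 3, 156816561 to 156816961). It held 49 and 29 reads under sgNT and 1 and 2 under sgAHR, or 31.7 ± 12.4 against 1.92 ± 0.426 normalized reads (SD, n = 2 each), a log2 difference of -3.44 ± 0.55 (SE, limma adjusted p = 0.00942). The same region lay 109.8 kb from the nearer end of TIPARP, a poly(ADP-ribose) polymerase gene induced by AHR. The next 9 regions had log2 differences of -2.56 to -2.17. Of these, 5 lay inside genes, namely PPP2R5C (-2.37), a regulatory subunit of phosphatase 2A, ACBD6 (-2.26), SSH1 (-2.56), a cofilin phosphatase, FOXP1 (-2.33), a transcription factor of naive T cells, and RBMS1 (-2.17). The other 4 lay outside the nearest gene body, which was ADGRG5 (-2.36, at 14050 bp), POLR3GL (-2.26, at 539 bp), BTG2 (-2.19, at 15520 bp) or TNFRSF11A (-2.35, at 29348 bp). These 9 had limma adjusted p-values of 0.00991 to 0.00995.

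In all, 85 of 8828 regions were lower and 1 was higher in sgAHR (limma, Benjamini-Hochberg adjusted p under 0.05), with 1339 at an unadjusted p under 0.05. Of the regions tested, 5252 had a peak in sgNT lists of replicates 1 and 2 only, and 556 in sgAHR lists only. The first class held 75 of the 85 lower regions. Peaks were called in the same libraries, so the choice of regions may enter the excess of lower calls. The single higher region lay 31983 bp outside NID1 (chromosome 1, 236097073 to 236097473), at 19 and 13 reads against 28 and 34 (log2 difference 1.63, adjusted p = 0.0359). The other 4 regions with the smallest p on that side did not pass, among them those in LIAT1 (log2 difference 1.56) and on chromosomes 1 (1.54) and 6 (1.93), the last pair with no protein-coding gene within 50 kb. Of the 85 lower regions, 81 (95.3%) overlapped a peak of sgNT replicate 3, a library with no column in the table, against a median of 85.9% in random region sets matched on the sgNT mean.

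The number of calls depended on the scaling and on single libraries. Median centring and quantile normalization left 0 calls in either direction, with 1187 and 1039 regions at an unadjusted p under 0.05, and TMM factors left 1 lower region. With median centring the median log2 difference over all regions moved from -0.18 to -0.02, and the smallest limma adjusted p was 0.0997. On the recovered reads, edgeR called 156 lower and 11 higher regions, or 40 and 6 with TMM factors. DESeq2 called 0, with 331 of 8828 regions at an unadjusted p under 0.05, a smaller share than the 0.05 given by chance. Libraries were also scaled by the value of 1 fragment in each library's coverage. Such scaling does not equalise the regions' totals and assumes that equal values mean equal depth. With it limma called 1672 lower and 0 higher regions, and the median log2 difference over all regions moved from -0.18 to -0.82. Of the 1672, 1410 were among the 5252 regions with a peak in sgNT lists of replicates 1 and 2 only. Lower and higher calls numbered 1 and 0 without sgNT replicate 1, 33 and 72 without sgNT replicate 2, 531 and 107 without sgAHR replicate 1 and 180 and 27 without sgAHR replicate 2. The 1 region called without sgNT replicate 1 was not among the 85 lower regions. The sign of all 85 lower regions was negative under each of these settings. They were picked from the same libraries at log2 differences of -3.44 to -1.54, so their sign had little room to turn. The libraries did not group fully by guide in pairwise correlation of log2 values across regions, which are not independent replicates. The sgAHR libraries had r = 0.725 with each other, sgNT replicate 2 had r = 0.691 with sgNT replicate 1 and r = 0.732 and r = 0.668 with sgAHR replicates 2 and 1, and sgNT replicate 1 had r = 0.534 and r = 0.510 with sgAHR replicates 1 and 2.

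**Figure D2:**
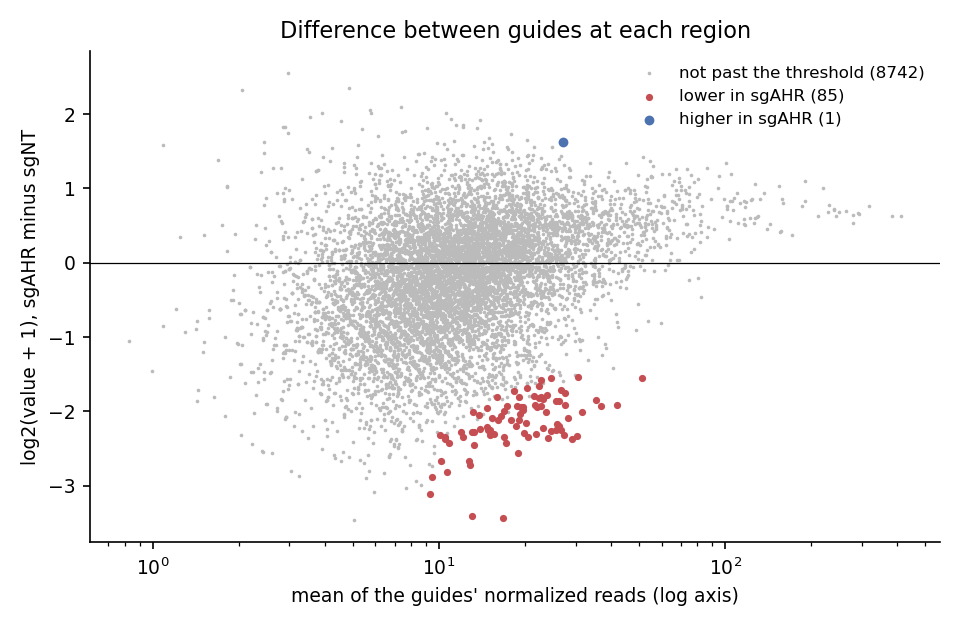
Log2 difference in normalized reads plus 1 (sgAHR minus sgNT, 2 libraries per guide) against the mean of the guides' normalized reads on a log axis, 1 point per region. The 85 lower regions lie between log2 differences of -3.44 and -1.54, and the 1 higher region is the one near NID1.

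Other genes named by the study's question did not pass over all regions. At CXCL13, the chemokine gene in the series title, the region inside the gene (chromosome 4, 77586912 to 77587312) held 26 and 26 reads under sgNT and 2 and 8 under sgAHR (log2 difference -1.77 ± 0.51, SE, limma adjusted p = 0.0915, n = 2 per guide). It reached an adjusted p of 0.00116 with the coverage-step scaling. At AHR itself the strongest region held 11 and 17 against 7 and 8 reads (log2 difference -0.13, adjusted p = 0.93), a difference that turned positive with median centring. JUN, the AP-1 subunit named in the series title, had 44 and 39 reads against 21 and 22 (log2 difference -0.21, adjusted p = 0.827). The strongest regions at MAF (-0.86), IL21 (-0.55), BCL6 (-0.29), IL22 (-0.57), IFNG (-0.39) and IL2RA (-1.35) did not pass either. With the coverage-step scaling, which called 1672 of all 8828 regions lower, those of IL2RA (limma adjusted p = 0.00317) and MAF (adjusted p = 0.0300) did. So did 23 of the 53 uncalled named regions in all. Those at NQO1 (0.13), RORA (0.27) and PRDM1 (0.11) lay above 0 on the deposited scaling and below 0 on the coverage-step scaling.

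**Figure D3:**
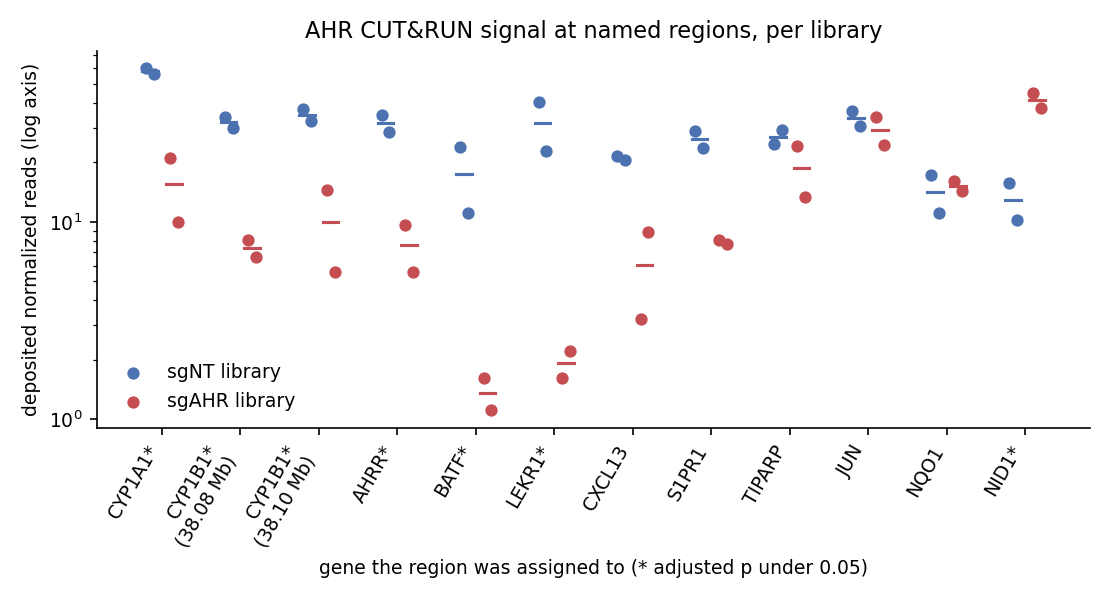
Deposited normalized reads (log axis) in each of the 4 libraries of the table at 12 regions, labelled by gene; short lines are guide means (n = 2 per guide) and an asterisk marks a limma adjusted p under 0.05. Both sgAHR libraries lie below both sgNT libraries at CYP1A1, CYP1B1, AHRR, BATF and LEKR1, and above them at NID1.

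Among gene lists fixed from prior knowledge, canonical AHR targets were lower relative to all other regions in camera with its preset correlation (adjusted p = 0.000396 over 13 lists). The call was lost with an estimated correlation (adjusted p = 0.809, unadjusted p = 0.219). The list had 24 regions at 12 of its 17 genes, with a median log2 difference of -0.98, and 4 regions were lower over all regions tested, those of CYP1A1, CYP1B1 (2 regions) and AHRR. Adjusted over the list alone, 6 regions were lower, among them that of NFE2L2, the oxidative stress regulator (-1.09). Both sgAHR libraries lay below both sgNT libraries at 15 of the 24 regions, against 16.7% of regions by chance and 30.3% of all regions here. TIPARP (-0.55) and NQO1 (0.13) did not pass. With the coverage-step scaling 12 of the 24 regions were lower, TIPARP among them (-1.24, limma adjusted p = 0.0423), and NQO1 was at -0.54 and did not pass.

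Genes of tissue residency and migration were also lower as a list in camera with the preset correlation (adjusted p = 0.0101). The call was lost with an estimated correlation (adjusted p = 0.809) and without sgNT replicate 1 (adjusted p = 0.0577 with the preset correlation). Its 26 regions at 9 genes had a median log2 difference of -1.04, with 0 regions lower over all regions tested and 3 adjusted over the list alone. These were regions near S1PR1 (-1.61) and inside S1PR4 (-1.91), both sphingosine phosphate receptors of lymphocytes, and near GPR15, a homing receptor of the gut (-1.63). The region of RUNX3 on the same list had a log2 difference of 0.70 and did not pass.

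The AP-1 family had 21 regions, of which 1 was lower, that of BATF. Regions of 1 gene went both ways, with 0.85 inside JUND and -0.58 outside it, and with 1.06 at 12009 bp outside FOS and -0.06 inside it, where its reads were highest. JUNB (0.39) lay at -0.22 on the coverage-step scaling, FOSL2 had -0.88, and none of these passed. The list did not pass in camera (adjusted p = 0.721). The T follicular helper and CXCL13 program had 21 regions with a median of -0.55, 0 lower over all regions and 1, at CXCL13, adjusted over the list alone. SH2D1A (-2.42) and CD200 (-1.06) were its next members, and the camera adjusted p was 0.173. Regulatory T cell genes had a median of -0.47 with IL2RA (-1.43), TGFB1 (-1.06) and IKZF2 (-1.77) and a camera adjusted p of 0.173, which was 0.0239 without sgNT replicate 2 and 0.785 without sgNT replicate 1.

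Further T cell lists and the housekeeping list held 0 lower and 0 higher regions on the deposited scaling and did not pass in camera. With the coverage-step scaling 1672 of all 8828 regions were lower. Among them were 11 of 52 regions of T cell activation, 7 of 19 of the type I interferon response and 3 of 6 of Th2. Housekeeping genes had 2 of 15, and the Th1 and the Th17 and Th22 lists 0. These list counts were not tested against the count over all regions. The type I interferon response had a median of -0.59 over 19 regions (adjusted p = 0.254), with RSAD2 (-1.41) and IFNAR1 (-1.19) among the members with the smallest p. T cell activation genes had a median of -0.32 over 52 regions (adjusted p = 0.423), with NFATC2 at -1.13 and NFKB1 at -1.94. The Th2 list had -0.74 over 6 regions (adjusted p = 0.35), with STAT6 (-1.26), IL4R (-0.76) and GATA3 (-0.73). The Th17 and Th22 list had -0.40 over 10 regions (adjusted p = 0.721), with IL23R at -1.69 and CCR4 at -1.72. The Th1 list had a median of -0.39 and a camera direction that was up, over 11 regions (adjusted p = 0.972), with RUNX3 at 0.70 and STAT4 at -0.90. Housekeeping genes had a median of -0.16 over 15 regions (adjusted p = 0.721), with EEF1A1 at -2.26 and PPIA at 1.04.

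Marker genes of other blood cells had few regions. Natural killer and CD8 genes had 6 regions with a median of -0.99 (camera adjusted p = 0.173), with GZMB (-0.99), KLRF1 (-0.997) and KLRD1 (-0.91), and activated CD4+ cells can also use GZMB. The B cell list had 2 regions, that of BLK (-1.26) among them, with a negative median of -0.20 and a camera direction that was up (adjusted p = 0.721), and the single monocyte region, near LYZ (0.60), was not tested.

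Lower regions lay mostly away from gene ends. Of the 85 lower regions, 14 (16.5%) were within 1000 bp of the end of a protein-coding gene, against 50.7% of all 8828 regions (odds ratio 0.190, Fisher's exact two-sided p = 8.83e-11, with regions treated as independent), and 47 lay inside a gene body. With the coverage-step scaling the share was 520 of 1672 lower regions (31.1%, odds ratio 0.366). Over all regions the median log2 difference was 0.00 near gene ends and -0.46 farther away, a difference of 0.46 (camera p = 1.18e-06, and p = 0.00642 with an estimated correlation). Without sgAHR replicate 2 this difference was 0.27. With the coverage-step scaling the medians were -0.65 near gene ends and -1.08 farther away. The deposited scaling sets equal totals, so the 0.00 does not mean an unchanged signal. Regions with a peak in sgNT lists of replicates 1 and 2 only numbered 5252 and had a median of -0.52, the 3020 with a peak under both guides had 0.20, and the 556 with a peak in sgAHR lists only had 0.69. These classes come from peaks called in the same 4 libraries, so the order of their medians follows in part from the split. The 222 regions more than 1 Mb from any protein-coding gene had a median of 0.78, and 0.11 with the coverage-step scaling.

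**Figure D4:**
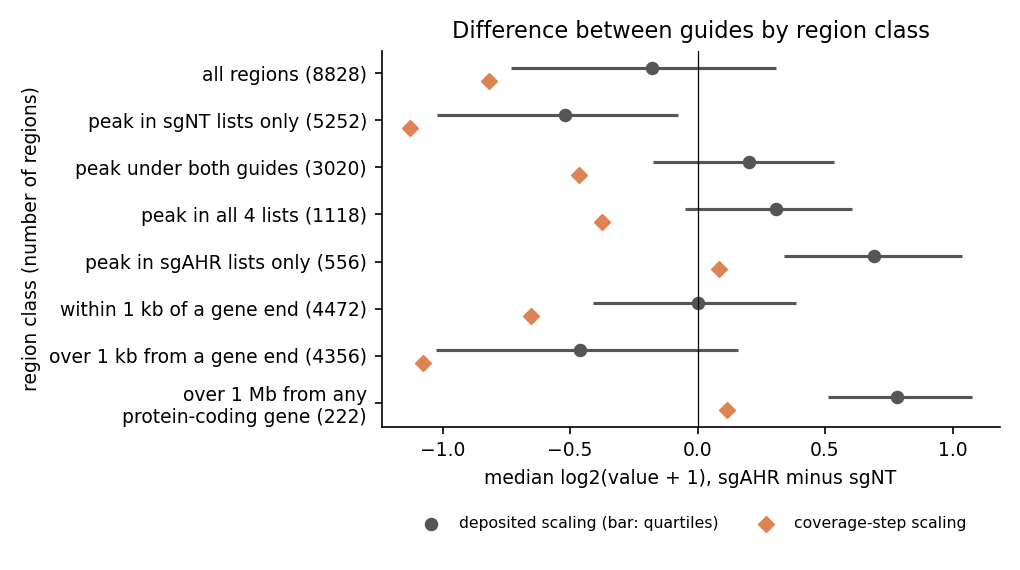
Median log2 difference (sgAHR minus sgNT, normalized reads plus 1) by region class, with the number of regions in brackets; circles use the deposited scaling with bars from the lower to the upper quartile of regions, and diamonds the coverage-step scaling. The median over all regions is -0.18 on the deposited and -0.82 on the coverage-step scaling, and regions more than 1 Mb from any protein-coding gene lie above 0 on both.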

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

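Coverage-step scaling, edgeR with TMM factors, DESeq2 with its own size factors, the subset with peaks under both guides and common peak thresholds were chosen after seeing the data. The cause of the changes below was not tested unless stated. The 16 called named regions kept their sign under each of 20 alternatives of the region fit that tested them (the subset with peaks under both guides held 2 of the 16). Of 53 uncalled ones, 12 changed sign in at least 1. The called regions had been picked for large differences in the same libraries, so this contrast follows in part from that choice. The median region held 7 to 14 reads per library, and the part of depth in the number of calls was not separated from that of the number of libraries. Against 85 lower and 1 higher regions, a pseudocount of 5 gave 163 and 7 and TMM factors 1 and 0. Median centring and quantile normalization gave 0 and 0 each. On whole reads edgeR gave 156 and 11, or 40 and 6 with TMM factors. DESeq2 gave 0 and 0 (331 of 8828 at an unadjusted p under 0.05), also with its own size factors (3.05% of regions). Both shares were below the 0.05 given by chance. Coverage-step scaling gave 1672 and 0 with limma, 1842 and 0 with edgeR and 117 and 0 with DESeq2, as it leaves the regions' totals unequal. That DESeq2 fit gave no adjusted p for 5819 of the 8828 regions. The 3020 regions with a peak under both guides gave 0 and 0 (266 at an unadjusted p under 0.05 in limma), and hold 10 of the 85. Leaving out 1 library, which leaves a guide with 1 library assumed to vary like the others, gave 1 to 531 lower and 0 to 107 higher regions. With the replicate number as a block, 489 regions were lower and 319 higher. Nothing in the labels says that a number marks a shared donor or day, and the correlation of the replicate differences of the guides, 0.210 over 2 pairs, leaves the pairing open.

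The list of canonical AHR targets moved from a camera adjusted p of 0.000396 to 0.809 with an estimated correlation. Tissue residency and migration moved from 0.0101 to 0.809, and reached 0.0160 to 0.0577 with 1 library left out. In fry, which tests for a change on balance and not against other regions, both lists had an adjusted p of 0.206. Of results that had not passed, the log2 difference changed sign with coverage-step scaling in limma, edgeR and DESeq2 at NQO1 (-0.54, -0.59, -0.60), JUNB (-0.22, -0.25, -0.25), RORA (-0.37, -0.64, -0.65), PRDM1 (-0.54, -0.63, -0.64) and, in edgeR and DESeq2, RUNX3 (-0.080, -0.083). AHR reached 0.029 with median centring, 0.13 with quantile normalization, 0.029 with TMM factors and 0.033 with DESeq2's own size factors, and BCL6 0.024 with quantile normalization. The Th1 list was up in camera and down in fry (adjusted p = 0.802), which answers another question. Its camera direction turned within 100 kb (adjusted p = 0.213) and with median centring (0.995), and that of the Th17 and Th22 list with quantile normalization (0.893) and coverage-step scaling (0.946). With 1 library left out, the log2 difference ranged from -0.17 to 0.43 at NQO1, -0.39 to 0.13 at AHR, -0.44 to 0.020 at JUN, -1.79 to 0.034 at FOSL2, -1.18 to 0.036 at IL22, -0.53 to 1.07 at RORA, -0.32 to 0.54 at PRDM1, -0.84 to 0.052 at IFNG and -0.37 to 1.57 at LYZ. The adjusted p ranged from 0.424 to 0.702 for the Th1 list, 0.510 to 0.782 for housekeeping and 0.412 to 0.712 for B cell genes, with turns in camera direction.

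Peak differences were -1958 among peaks above the median maximum signal, -1935 in the upper part of each list by maximum signal, above its median, and -30 at a common threshold of 6 lists, against -3883. The share of sgNT places in 0 sgAHR lists was 58.1% with reciprocal overlap, 53.0% above the median maximum signal and 39.0% to 65.6% with 1 library left out. Motif and GC alternatives, the batch term and the fit without replicate 3 were not run. A gene end within 3000 bp and coverage-step scaling left the gene end difference at 0.47 and 0.42.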

Other observations

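All tests of explanations in this part were chosen after the results they bear on were seen, though some of the alternatives they cite were planned. The loci and region classes it names were also picked after that, though AHRR and IL4R fall under the naming rule as well. At several loci all regions had lower values under sgAHR, though few of them passed the test. At GPR55, a lipid receptor gene, all 6 regions between 230905771 and 230974631 on chromosome 2 were lower in both sgAHR libraries than in both sgNT libraries, with summed reads of 152 and 96 against 17 and 22 and 2 regions called lower. At AHRR all 5 regions between 333369 and 400214 on chromosome 5 behaved so, with log2 differences of -1.95 to -1.19, and at CD96, an immune receptor of T and natural killer cells, all 6 did, with -1.52 to -0.43 and none called. The 4 regions of LMNA, the lamin A gene, had a median of -1.27 with 1 called, the 4 of ASB2 a median of -1.75 with none called, and the 3 of IL4R, the IL-4 receptor gene, -0.76 to -0.52 with none called. Of 414 genes with at least 3 regions, 28 had every region lower in both sgAHR libraries and 2 every region higher. Shuffling the regions among those of like signal and distance to gene ends gave a median of 14 such genes and at most 30 in 1000 shuffles (permutation p = 0.002).

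Strong sites picked by a library outside the table had a ratio of reads nearer to 1 than all regions did. The 102 regions in the 100 strongest peaks of sgNT replicate 3 held 9225 and 9879 recovered reads under sgNT and 6035 and 8877 under sgAHR, a ratio of 0.781, where all regions had a ratio of 0.613 and the 85 lower regions 0.135. Of the 102, the 56 within 1000 bp of a gene end had a ratio of 0.849. These ratios were not tested, and the sets were chosen in unlike ways. The 85 were picked for low sgAHR values, and 5252 of all regions had a peak in sgNT lists of replicates 1 and 2 only. Between single libraries, sgAHR over sgNT ran from 0.611 to 0.962 in the 102 regions and from 0.488 to 0.744 over all regions. The 15 peaks of sgAHR replicate 3 were all in the list of sgNT replicate 3, with a median percentile of 99.8 by total signal, and 12 were in all 5 other lists. They lay at or near U2AF2, RPL28, PIK3R2, TMEM80, GSK3B, ZC3H4, C14orf119, RABEP2, CDC27, C1QTNF6, ZNF557, MTA2, TP53RK, IFT140 and MBOAT7.

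The first pattern is the excess of 85 lower over 1 higher region, which turned to 33 lower and 72 higher without sgNT replicate 2. Fewer fragments in the sgAHR libraries, as the whole cause, would lower all sites by a common factor. The 133 regions more than 1 Mb from any protein-coding gene with an sgNT peak kept 1.01 times the sgNT reads, against 0.613 over all regions. In the 70 of them in sgNT lists only the ratio was 0.919. The handling of duplicate and multiply mapped reads is not given, so whether reads in these regions follow depth is not known. A choice of regions for chance-high values in sgNT replicates 1 and 2 alone would not raise their overlap with sgNT replicate 3. Of the lower regions, 95.3% overlapped a peak there, against a median of 85.9% in 10000 region sets matched on the sgNT mean, of which 17 reached that share. The sets were not matched on agreement between sgNT replicates 1 and 2 or on distance to gene ends, so a part for the choice of regions stays open. The number of calls moved with the scaling, with 0 lower regions under median centring and 1672 with coverage-step scaling. On the deposited scaling it also moved with the tool (156 in edgeR, 0 in DESeq2) and with 1 library left out. How many regions had a lower signal under sgAHR therefore stays open. Loss of AHR is a candidate explanation for the lower regions as a hypothesis, and antibody efficiency or cell number, which may differ by guide, was not tested.

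The second pattern is that gene-free regions, more than 1 Mb from any protein-coding gene, leaned to sgAHR in the deposited values, with a median log2 difference of 0.78 over 222 regions, the largest groups being 37 on chromosome 1 between 122553734 and 124771276, 28 on chromosome 5 between 47296919 and 49368467 and 28 on chromosome 19 between 25247963 and 27793922. Listing for chance-high sgAHR values, as the whole cause, was taken to give a negative median where peaks were in sgNT lists only. The 70 such regions had 0.57. The deposited scaling raises sites that did not change, so a median above 0 cannot decide this. A background that did not change, taking a larger share of a smaller total, may account for it, since coverage-step reads in the 222 regions were 1.11 times the sgNT level, a value that assumes equal depth at equal coverage steps. The ratio moved with the listing, from 0.927 in the 70 listed under sgNT only to 1.28 in the 89 listed under sgAHR only. It was 1.02 in the 133 that have an sgNT peak. A part for the listing therefore stays open. Antibody-independent cutting is a possible form of such a background, and no biological explanation was tested. Whether the stretches that hold these regions are made of repeats was not examined here. The handling of multiply mapped reads is not given, so they may not stand for gene-free sequence in general.

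The third pattern is the 15 peaks of sgAHR replicate 3. A shortage of fragments large enough to remove most peaks would lower the heights of those left, but its maximum in fragments had a median of 0.911 times that of sgNT replicate 3 over 15 sites. Against the other lists the medians were 0.746 (sgNT replicate 1, 14 sites), 0.714 (sgNT replicate 2, 15 sites), 0.971 (sgAHR replicate 1, 12 sites) and 0.680 (sgAHR replicate 2, 14 sites), so a smaller shortage stays open. Its weakest peak held 7.21 times the total fragment-bp of the highest minimum among the other lists, which a higher threshold at peak calling would give and a loss of weaker sites would give too. These cannot be told apart from a list that holds strong peaks alone.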
